A study of Mus musculus with 18 samples.

How the data were processed

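RNA from the cerebellum of FVB mice was extracted with TRIzol and RNeasy columns, made into Illumina TruSeq libraries and sequenced. The authors aligned the reads to mm10 with TopHat2 2.0.11 and quantified them with Cufflinks 2.2.1. The deposited values are FPKM (fragments scaled to transcript length and to mapped fragments per library) per gene symbol, normalized across the 18 libraries by the authors with Cuffnorm. The annotation, the read filters and the normalization method of Cuffnorm are not given in the sources used here. The columns meant for confidence bounds equal each other in every value and equal the FPKM in 99.8% of values, so they hold no interval and were not used. No counts or depths were available, so no counting intervals were computed. Of 22783 genes, 2608 were at 0 in every library and 21 values in 11 genes carried a failed status; 10 of these genes were among those tested. Chromosome positions came from the table itself, and 21521 of its symbols were found in GENCODE M21.

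Libraries were grouped by genotype and age as labelled, 3 in each of 6 groups. A pseudocount of 1 was added and log2 values were taken. The 13487 genes with an FPKM of at least 1 in at least 3 of the 18 libraries were tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend and a mean for each of the 6 groups, which left 12 residual degrees of freedom. There were 11 comparisons: the genotype effect at each of 3 ages and averaged over them, 3 interactions of genotype and age, and the age effects from week 5 to 12 and from week 12 to 28 in each genotype. P-values are two-sided and were adjusted by Benjamini and Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. The genes named were chosen by a rule fixed before the data were examined. It takes the largest changes in each direction among called genes (12 for genotype effects, 8 for interactions, 10 for age effects, with no overlap between groups for a single contrast of groups), up to 4 members of each described list with the smallest p, and Cck, Atxn1, Cckar, Cckbr and Pcp2. Where none passes, it takes the 5 with the smallest p. Where a named gene no longer passed without 1 library, the library given is the one with the highest adjusted p, and others did the same for some genes. Symbols of predicted or clone-named genes are counted but not named, and some genes the rule gives are summarised or left out. Tuba1a, Gucy1a3 and H2-D1 were named after their values were seen.

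The 32 gene lists, with 603 members of which 601 were in the table and 538 were tested, were also fixed before the data were examined. They cover cell types of the cerebellum and of neighbouring tissue, Purkinje cell functions and pathways. Each was tested with camera at a preset correlation of 0.01, with adjustment over the lists of a comparison, and again with a correlation estimated from the data. Fry, which asks whether the members of a list move in 1 direction on balance and does not compare the list with other genes, was run beside it. On simulated data made from these values, limma called 85.1% of genes changed by 0.5 (log2) and 100% of those changed by 1 at week 28, with 8 of 13262 unchanged genes called. The simulated noise was independent between genes and had the same spread in every group, so these rates may not hold for the real libraries. Alternatives set before the data were seen covered pseudocounts of 0.1 and 0.5, no filter, a mean FPKM of at least 5, median-ratio rescaling, quantile normalization, robust fitting, no trend, library weights, replicate numbers as blocks, Xist and choroid plexus levels as covariates, fits of the compared groups only and leaving out each library. After seeing the data, fits without 3 libraries low in choroid plexus genes and without 3 with both Xist and Y-linked genes were added. Data were handled with the R package data.table (version 1.17.8), pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9 under Python 3.11.15.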

Results

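RNA was sequenced from the cerebellum of FVB mice of 2 genotypes at 3 ages. The first genotype, Cck-/-, is labelled as lacking both copies of Cck, the gene of the neuropeptide cholecystokinin. The second, ATXN1[30Q]D776/Cck-/-, carries in addition a transgene for ataxin-1, the protein affected in spinocerebellar ataxia type 1 (SCA1), in a form with an aspartate at a site that is otherwise a phosphorylated serine. The 30Q of its label stands for a tract of 30 glutamines, and the label does not say whether that tract is expanded. Libraries of the second genotype are called transgenic below. Each genotype had 3 libraries at week 5, 3 at week 12 and 3 at week 28, 18 in all. The values were FPKM per gene symbol for 22783 genes, summing to between 389248 and 441509 per library. Between 12767 and 13323 genes reached an FPKM of 1 in a library. The highest sum came from the transgenic week 28 replicate 2, in which the small RNA gene AF357426 alone held 49462 FPKM; the other libraries summed to at most 423312. Read counts and depth are unknown, so no counting intervals are given. The labels do not say that the 3 libraries of a group came from separate animals. P-values and SEs of the main fit rest on 1 spread between libraries per gene, shared by the 6 groups. Correlations of log2 values within groups ran from 0.984 to 0.996, and between groups from 0.965 to 0.993.

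The series concerns cholecystokinin receptor signalling, the mTORC1 growth pathway and Purkinje cells, the output neurons of the cerebellar cortex, in ataxic mice. Cck itself (chromosome 9, 121489824 to 121495694, mm10) was above 0 FPKM in all 18 libraries, although every animal is labelled Cck-/-. In the Cck-/- libraries it stood at 20.8 ± 4.51 FPKM at week 5, 13.9 ± 2.74 at week 12 and 4.97 ± 2.06 at week 28 (mean ± SD, n = 3 each). In the transgenic libraries it stood at 98.1 ± 15.6 FPKM at week 5, 14.8 ± 2.21 at week 12 and 6.51 ± 1.76 at week 28. The transgenic libraries were thus higher at week 5 (log2 fold change 2.19, SE 0.23, adjusted p = 5.82e-05; limma). At week 12 the difference was 0.095, SE 0.23, adjusted p = 0.936, and at week 28 it was 0.36, SE 0.23, adjusted p = 0.353 (limma). A value per gene does not show which exons the reads came from, and no library with intact Cck was analysed here, so these values do not settle the state of the Cck alleles. The 3 libraries concerned are named as labelled, ATXN1[30Q]D776/Cck-/- at week 5. Cckar, which encodes the CCK1 receptor, lay between 0.00714 and 0.0838 FPKM and was too low to test. Cckbr, the gene of the other receptor, stood at 1.10 ± 0.653 FPKM in Cck-/- and 1.37 ± 0.544 in transgenic libraries at week 28 and was called in none of the 11 comparisons by limma. Mouse Atxn1 stood at 5.28 ± 0.632 and 6.05 ± 0.632 FPKM at week 5 and at 5.74 ± 1.51 and 5.96 ± 0.461 at week 28, and was called in none of them either. Reads of the human transgene were not analysed here.

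**Figure D1:**
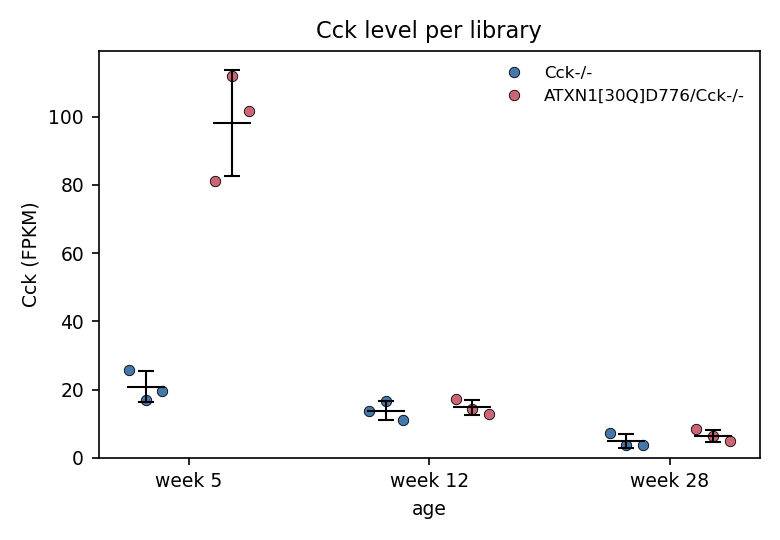
Cck level in FPKM on the vertical axis against age on the horizontal axis, with a point for each of the 18 libraries, blue for Cck-/- and red for ATXN1[30Q]D776/Cck-/-; bars give the mean and SD of 3 libraries. The 3 transgenic week 5 libraries average 98.1 FPKM and lie above the other 15, which reach at most 25.8.

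The genotype effect at week 5 compares transgenic with Cck-/- libraries in young animals. Cck stood at 98.1 FPKM in these transgenic libraries, against 20.8 in Cck-/- and 14.8 and 6.51 in transgenic libraries of weeks 12 and 28. What goes with the transgene therefore cannot be told apart here from what goes with this level of Cck or its cause. The same holds for the averaged effect, the interactions with week 5 and the transgenic change from week 5 to 12. In all, 18 of 22 genes of cholesterol synthesis, 10 of 23 of myelin, the sheath made by oligodendrocytes, and 7 of 27 of Purkinje cell identity were lower in the transgenic than in the Cck-/- libraries. For cholesterol synthesis and blood genes the Cck-/- week 5 libraries had the highest mean of the 6 groups: their mean log2 level was 4.73 ± 0.067 for cholesterol synthesis, against 4.31 ± 0.054 in the transgenic week 5 libraries and 4.10 to 4.21 in the other 4 groups. For blood it was 6.64 ± 0.37, against 5.16 ± 0.21 and 4.81 to 5.74. Myelin genes stood at 6.30 ± 0.12 and 5.92 ± 0.016 at week 5 and at 5.41 to 5.73 in the other 4 (mean ± SD, n = 3). Opn3, which encodes an opsin, and Mdfi, an inhibitor of myogenic transcription factors, fell (log2 fold change -2.14, SE 0.15, adjusted p = 2.11e-06 and -1.69, SE 0.10, adjusted p = 6.25e-07; limma). Garnl3, Tmem255a and Atp2a3, an endoplasmic reticulum calcium pump, fell by 1.70, 1.61 and 1.36 on the log2 scale. Galr1, a galanin receptor, rose by 1.77, the phospholipase gene Pla2g4e by 1.64, the secretory granule protein gene Scg5 by 1.03 and the pro-apoptotic gene Hrk by 1.01. Serpina3n, a gene of reactive astrocytes, rose by 2.65 with a large SE of 0.59. Tuba1c, an alpha-tubulin gene, stood at 20.9 ± 1.47 against 2.27 ± 0.248 FPKM, while its near-identical relative Tuba1a stood at 414 ± 13.2 against 582 ± 7.11; the split of reads between such copies is uncertain.

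Of the 22 measured genes of cholesterol synthesis, 18 fell at week 5, 0 rose and 4 were not called (1 higher and 19 lower when adjusted over the list alone). Cyp51, Sc5d and Hmgcs1 changed by -0.82, -0.70 and -0.81 (log2). The list gave camera adjusted p = 7.13e-16, adjusted p = 0.372 with an estimated correlation, fry adjusted p = 0.00185 (limma). Of 23 oligodendrocyte and myelin genes, 10 fell and 0 rose (0 higher and 15 lower when adjusted over the list alone), among them Ugt8a and Fa2h, which make myelin lipids, at -0.75 and -0.50, Cnp at -0.47 and Tspan2 at -0.69. That list gave camera adjusted p = 5.64e-11, adjusted p = 0.467 with an estimated correlation, fry adjusted p = 0.0250 (limma). Of 27 Purkinje cell identity genes, 7 fell and 0 rose (1 higher and 9 lower when adjusted over the list alone): Car8 changed by -1.07, Gng13 by -0.90, Doc2b by -0.80 and Icmt by -0.63. Pcp2, an abundant Purkinje cell transcript, was not called (-0.16, SE 0.18, adjusted p = 0.673; limma), and the list gave camera adjusted p = 0.000202, adjusted p = 0.806 with an estimated correlation, fry adjusted p = 0.239. Of 29 genes of Purkinje cell calcium and mGluR1 signalling, 8 fell, including Casq2 (-0.75) and Atp2a2 (-0.42). For the calcium and mGluR1 list, camera gave adjusted p = 0.0122, adjusted p = 0.806 with an estimated correlation and fry adjusted p = 0.304 (limma). Of 14 genes of inhibitory interneurons, 5 rose (6 higher and 0 lower when adjusted over the list alone), among them Sorcs3, Tfap2b, Kit and Pax2 by 0.42, 0.32, 0.39 and 0.37, each of which lost its call without at least 1 library (highest adjusted p by limma 0.0570, 0.0751, 0.109 and 0.0992, without Cck-/- replicate 3, Cck-/- replicate 1, transgenic replicate 2 and Cck-/- replicate 3). Their list gave camera adjusted p = 0.000505, adjusted p = 0.467 with an estimated correlation, fry adjusted p = 0.0434 (limma). Of 41 mTORC1 pathway genes, Tbc1d7, a subunit of the TSC complex, was the single call (-0.31). In none of the 11 comparisons did any of the 32 lists pass camera with an estimated correlation.

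Cck stood at 98.1 ± 15.6 FPKM in the transgenic libraries used here. In all, limma called 1035 of 13487 genes at week 5, 445 higher and 590 lower in the transgenic libraries. Choroid plexus genes, from the tissue that makes cerebrospinal fluid, were low in 2 of the 3 transgenic libraries, with a mean log2 value of 0.99 in replicate 1 and 0.88 in replicate 2 against 3.75 in replicate 3 and 3.02 to 3.35 in the Cck-/- libraries, and blood genes had a median log2 fold change of -1.24 with no member called by limma (0 past the threshold and 2 at an unadjusted p under 0.05). The count fell to 545, 657 and 458 without Cck-/- replicate 1, 2 or 3, and to 501 and 676 without transgenic replicate 2 or 3. It was 309 without the 3 of all 18 libraries that were low in choroid plexus genes, which leaves transgenic replicate 3 alone in its group, assumed to vary like the libraries of the other groups. It was 666 without 3 in which Xist and Y-linked genes were both detected, and 3112 with library weights.

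At week 12 fewer genes passed, and most were lower in the transgenic libraries. Among the decreases were 9 of 27 Purkinje cell identity genes. Opn3, Fgf7 (a growth factor), Tmem255a, Garnl3 and Mdfi changed by -1.79 ± 0.15, -1.72 ± 0.21, -1.51 ± 0.19, -1.38 ± 0.21 and -1.32 ± 0.10 (log2 fold change ± SE). Strip2 changed by -1.14 ± 0.12. Among increases, Col4a1 and Col4a2, which encode basement membrane collagen, rose by 0.95 ± 0.14 and 0.66 ± 0.11, and Hrk rose by 0.98 ± 0.18.

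Of the 27 Purkinje cell identity genes, 9 fell at week 12 and 0 rose (0 higher and 20 lower when adjusted over the list alone). Icmt, which methylates prenylated proteins, changed by -0.92, Doc2b, a calcium sensor of vesicle release, by -1.01, Pde5a by -0.71 and the inositol trisphosphate kinase gene Itpka by -0.83. Pcp2 stood at 659.9 ± 65.4 against 698 ± 19.4 FPKM and was not called by limma (adjusted p = 0.923). The list had a median of -0.48 and gave camera adjusted p = 2.05e-19, adjusted p = 0.219 with an estimated correlation, fry adjusted p = 0.0277 (limma). Of 29 calcium and mGluR1 signalling genes, 8 fell (1 higher and 16 lower when adjusted over the list alone), including Atp2a3 (-1.29), Prkg1 (-0.75) and Atp2a2 (-0.55). For the calcium and mGluR1 list, camera gave adjusted p = 3.5e-17, adjusted p = 0.219 with an estimated correlation and fry adjusted p = 0.0277 (limma). Of the 6 genes first reported lower in Purkinje cells of SCA1 transgenic mice, 3 fell. For the SCA1 Purkinje list, camera gave adjusted p = 3.89e-10, adjusted p = 0.219 with an estimated correlation and fry adjusted p = 0.0122 (limma). Clec7a and Cd52 were the 2 called of 18 activated microglia genes and rose by 0.72 and 0.82 (10 higher and 0 lower when adjusted over the list alone; camera adjusted p = 9.08e-12, adjusted p = 0.239 with an estimated correlation, fry adjusted p = 0.0358; limma). Without transgenic replicate 2, Itpka, Clec7a and Cd52 no longer passed (adjusted p of 0.0556, 0.0772 and 0.205 by limma), and Hrk did not pass without Cck-/- replicate 1 (0.0590). Markers of other tissue had these mean log2 levels in transgenic against Cck-/- libraries: meninges 3.68 against 3.38, choroid plexus 3.08 against 2.51 and blood 5.45 against 5.37. Brainstem and cerebellar nuclei genes stood at 2.82 against 2.98, and midbrain and forebrain genes at 1.54 against 1.87. No member was called of the cholesterol synthesis list by limma (22 measured, median -0.00072), the myelin list (23, 0.19) or the mTORC1 list (41, -0.041); at an unadjusted p under 0.05, 1, 9 and 4 members did.

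Limma called 183 genes at week 12, 38 higher and 145 lower. The count was 85 and 90 without Cck-/- replicate 1 or 2, 59 without transgenic replicate 2, 63 when only these 6 libraries were fitted, 63 without the 3 libraries with both Xist and Y-linked genes, and 323 with library weights.

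At week 28, 24 of 27 Purkinje cell identity genes were lower in the transgenic libraries, and 10 of 22 homeostatic and 10 of 18 activated microglia genes were higher, lists that both passed fry (adjusted p = 0.0236 and 0.00608; limma) but not camera with an estimated correlation (adjusted p = 0.399 and 0.399). The Purkinje cell list too was past fry (adjusted p = 3.52e-05) and not past camera with an estimated correlation (adjusted p = 0.121). Whether these effects differ from those at week 12 was tested separately, by the interaction described further on, in which 0 genes passed by limma (1365 at an unadjusted p under 0.05). Atp2a3 changed by -2.24 ± 0.16, Fgf7 by -2.21 ± 0.21, Garnl3 by -1.90 ± 0.21 and Strip2 by -1.66 ± 0.12 (log2 fold change ± SE). Mslnl rose by 1.93 ± 0.20, Hrk by 1.86 ± 0.18, Galr1 by 1.69 ± 0.22, Nppb, a natriuretic peptide gene, by 1.19 ± 0.12 and Col4a1 by 1.05 ± 0.14. Gfap, the intermediate filament gene of astrocytes, rose from 95.5 ± 33.9 to 260.2 ± 72.9 FPKM.

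Of the 27 Purkinje cell identity genes, 24 fell at week 28, 0 rose and 3 were not called, with a median of -1.02 (0 higher and 24 lower when adjusted over the list alone). Car8, which encodes a regulator of the inositol trisphosphate receptor, fell from 373 ± 10.2 to 96.9 ± 32.4 FPKM (log2 fold change -1.99, SE 0.18, adjusted p = 1.2e-05; limma). Icmt changed by -1.68, Doc2b by -1.72 and Itpka by -1.62, and Pcp2 fell from 718 ± 33.5 to 338 ± 135 FPKM (-1.15, SE 0.18, adjusted p = 0.000769; limma). The list gave camera adjusted p = 6.06e-28, adjusted p = 0.121 with an estimated correlation, fry adjusted p = 3.52e-05 (limma). In the calcium and mGluR1 list 21 of 29 fell and 1, the guanylate cyclase gene Gucy1a3, rose, with camera adjusted p = 6.31e-18, adjusted p = 0.186 with an estimated correlation, fry adjusted p = 0.000131 (limma); Homer3 and Inpp5a changed by -1.34 and -1.21. All 6 genes first reported lower in SCA1 Purkinje cells fell, including Atp2a2 (-0.68). For the SCA1 Purkinje list, camera gave adjusted p = 8.11e-12, adjusted p = 0.121 with an estimated correlation and fry adjusted p = 1.78e-05 (limma). Of 21 ion channel genes of Purkinje cell firing, 9 fell, among them the potassium channel subunit genes Kcnip1 and Kcnab1 at -0.97 and -1.08. For the ion channel list, camera gave adjusted p = 0.000204, adjusted p = 0.399 with an estimated correlation and fry adjusted p = 0.0236 (limma).

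**Figure D2:**
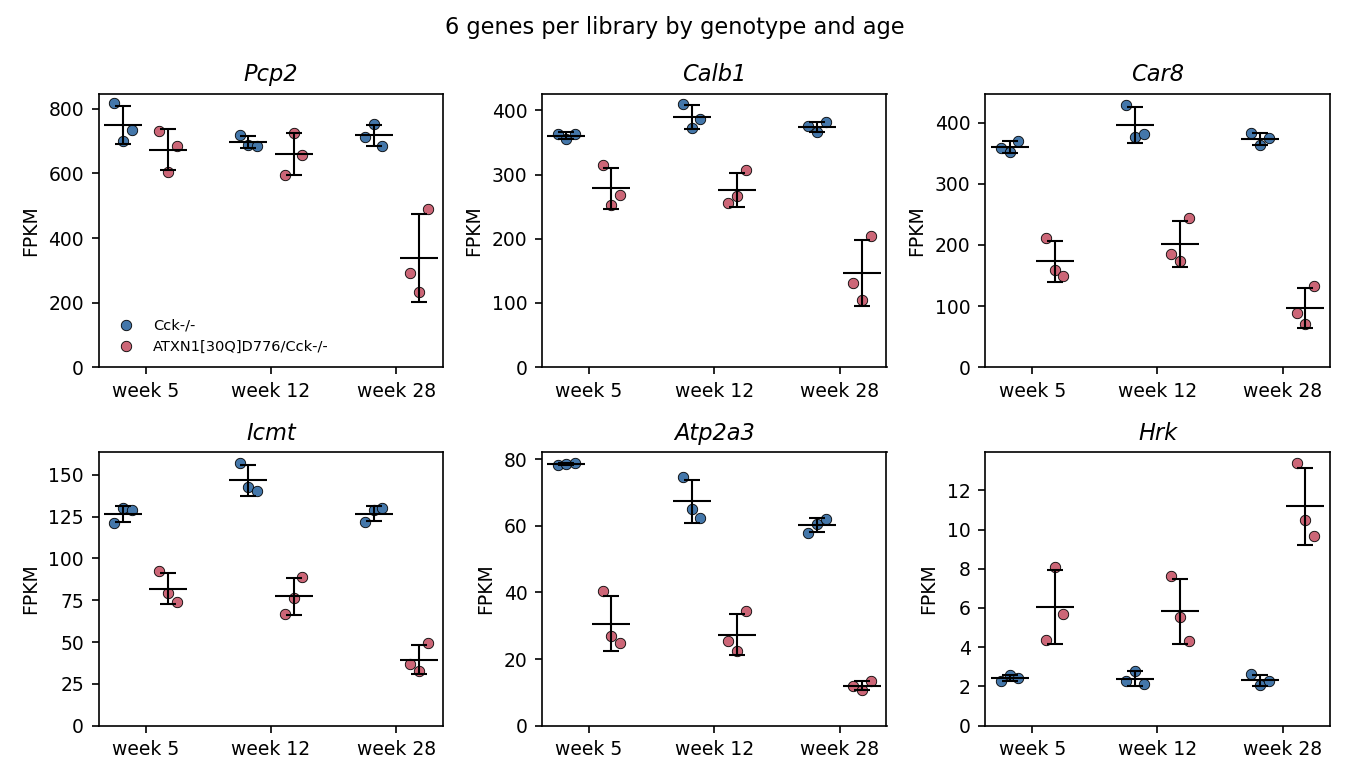
Levels in FPKM on the vertical axes of the Purkinje cell genes Pcp2, Calb1, Car8 and Icmt, the calcium pump gene Atp2a3 and the pro-apoptotic gene Hrk at weeks 5, 12 and 28, with a point per library, blue for Cck-/- and red for ATXN1[30Q]D776/Cck-/-, and the mean and SD of 3 libraries as bars. At week 28, Pcp2 stands at 718 FPKM in Cck-/- and 338 in transgenic libraries, on average.

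Of 22 homeostatic microglia genes, 10 rose at week 28 and 0 fell (18 higher and 0 lower when adjusted over the list alone). Trem2 and Tyrobp, a receptor and its adaptor, rose by 1.04 and 0.94, Aif1 by 0.64 and P2ry13 by 0.50, and the list gave camera adjusted p = 5.08e-10, adjusted p = 0.399 with an estimated correlation, fry adjusted p = 0.0236 (limma). Of 18 activated microglia genes, 10 rose, including Clec7a (1.01), Cd68 (0.99), Cd84 (0.54) and Lgals3 (0.81). For the activated microglia list, camera gave adjusted p = 2.75e-09, adjusted p = 0.399 with an estimated correlation and fry adjusted p = 0.00608 (limma). Of 18 reactive astrocyte genes, 6 rose and 1, the histocompatibility gene H2-D1, fell: Gfap changed by 1.45, the complement gene C4b by 1.14 and Cd44 by 0.90. For the reactive astrocyte list, camera gave adjusted p = 0.000712, adjusted p = 0.464 with an estimated correlation and fry adjusted p = 0.0541 (limma). Genes of Bergmann glia and astrocytes moved both ways, 2 higher and 6 lower of 21: Aqp4 (a water channel) and Gja1 (a gap junction protein) rose by 1.04 and 0.73, while the glutamate transporter gene Slc1a3 and Fabp7 changed by -0.72 and -0.66. That list had a median of 0.10 and a mean of -0.012, which differ in sign, and camera gave adjusted p = 0.555, adjusted p = 0.888 with an estimated correlation and fry adjusted p = 0.645 (limma). Of 23 myelin genes, 7 rose (17 higher and 0 lower when adjusted over the list alone), with Mbp at 0.44, Fa2h at 0.29, Myrf at 0.41 and Sox10 at 0.40 and camera adjusted p = 5.33e-08, adjusted p = 0.399 with an estimated correlation, fry adjusted p = 0.0321 (limma). Of 35 oxidative phosphorylation genes, 4 fell, Cox7c, Cycs, Ndufa1 and Ndufa4, by between 0.25 and 0.29 on the log2 scale. For the oxidative phosphorylation list, camera gave adjusted p = 4.17e-07, adjusted p = 0.502 with an estimated correlation and fry adjusted p = 0.0587 (limma). Of 41 mTORC1 pathway genes, Akt2, a kinase upstream of the complex, and Rheb, its activating GTPase, were called, at -0.37 and -0.19, and the list gave camera adjusted p = 0.0690, adjusted p = 0.399 with an estimated correlation, fry adjusted p = 0.00824 (limma). Without transgenic replicate 2 the adjusted p by limma was 0.0619 for Aif1, 0.0729 for P2ry13, 0.0716 for Fabp7, 0.0641 for Mbp, 0.0776 for Fa2h, 0.110 for Myrf, 0.111 for Sox10, 0.0970 for Cox7c, 0.110 for Cycs, 0.125 for Ndufa1, 0.163 for Ndufa4, 0.0506 for Akt2 and 0.140 for Rheb, so that these 13 no longer passed.

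Limma called 1439 genes at week 28, 612 higher and 827 lower. Choroid plexus genes were low in transgenic replicate 3, with a mean log2 value of 1.11 against 2.87 to 3.70 in the other 5 libraries, and that library's Purkinje cell list averaged 5.39 against 4.97 and 4.77 in transgenic replicates 1 and 2 and 6.02 to 6.08 in Cck-/-. The count was 752 and 959 without Cck-/- replicate 2 or 3, and 721 and 618 without transgenic replicate 1 or 2. It was 337 when only these 6 libraries were fitted, 668 without the 3 libraries with both Xist and Y-linked genes, and 5835 with library weights.

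**Figure D3:**
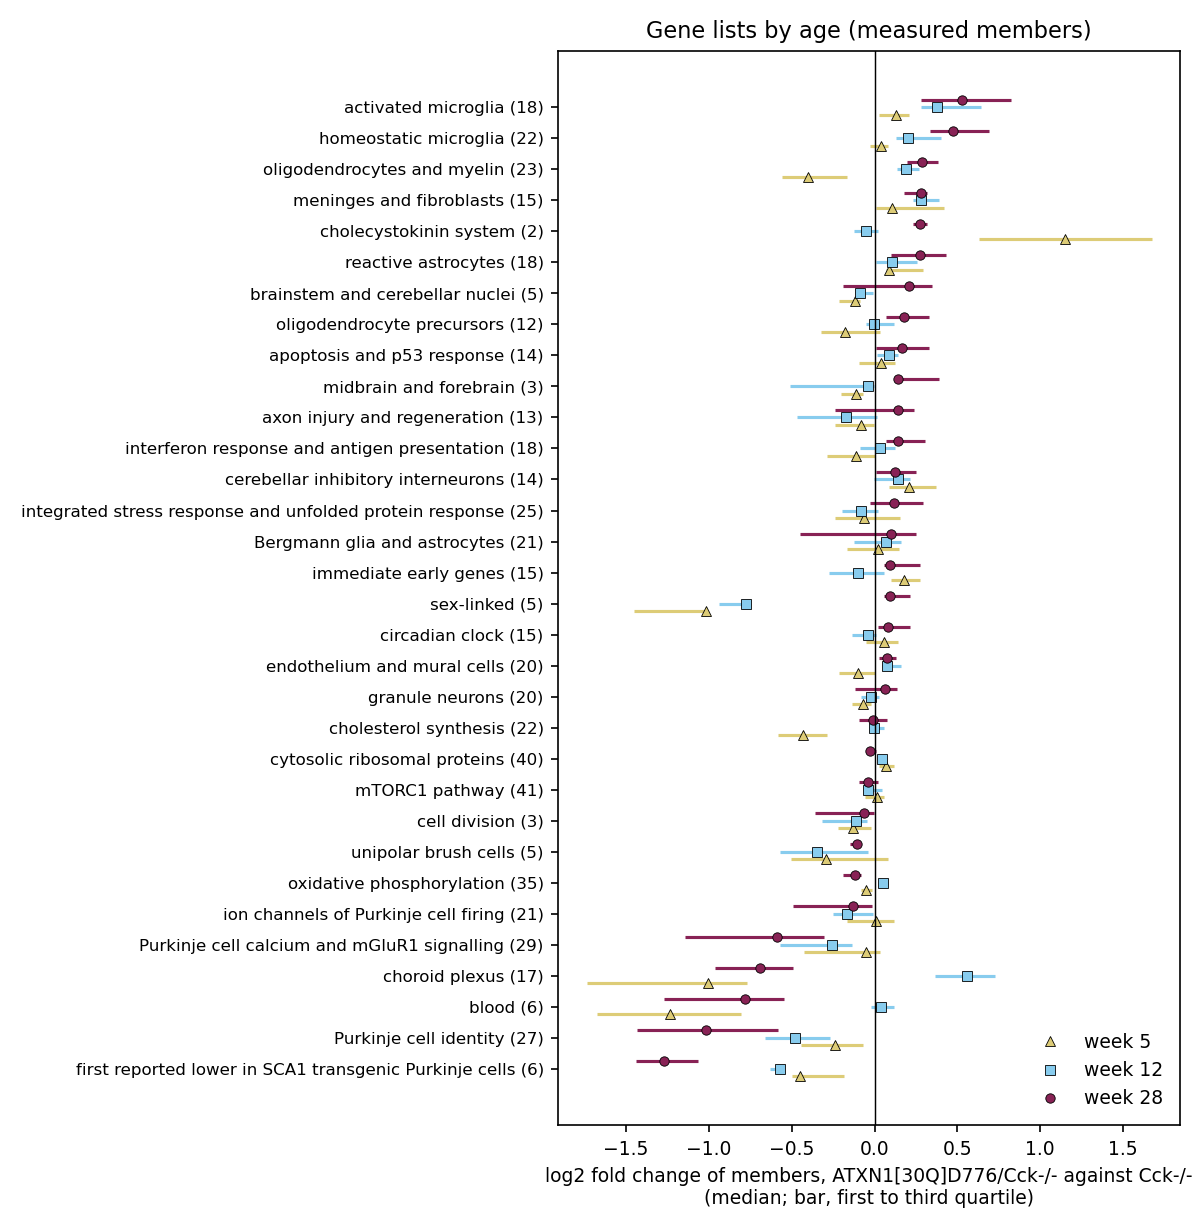
Log2 fold change of ATXN1[30Q]D776/Cck-/- against Cck-/- on the horizontal axis for the measured members of 32 gene lists, at weeks 5 (triangles), 12 (squares) and 28 (circles); symbols give the median over members and bars the quartiles on either side. The Purkinje cell identity list has medians of -0.24, -0.48 and -1.02 at the 3 ages, the cholesterol synthesis list -0.43 at week 5, and the choroid plexus list, low in 3 libraries, -1.01, 0.56 and -0.69.

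By limma, 104 genes were called lower at all 3 ages, 13 were called higher at all 3, 1880 were called at exactly 1 age and 22 were called in opposite directions at 2 ages. Averaged over ages, Opn3 changed by -1.85 ± 0.089, Garnl3 by -1.66 ± 0.12, Fgf7 by -1.65 ± 0.12, Atp2a3 by -1.63 ± 0.091, Mdfi by -1.49 ± 0.059, Car8 by -1.35 ± 0.11 and Strip2 by -1.32 ± 0.069 (log2 fold change ± SE). Galr1, Hrk and Mslnl rose by 1.44 ± 0.13, 1.29 ± 0.10 and 1.18 ± 0.11. Of 27 Purkinje cell identity genes 22 fell, with camera adjusted p = 1.85e-22, adjusted p = 0.225 with an estimated correlation, fry adjusted p = 3.84e-05 (limma), and of 18 activated microglia genes 15 rose. For the activated microglia list, camera gave adjusted p = 1.42e-10, adjusted p = 0.295 with an estimated correlation and fry adjusted p = 0.00106 (limma). Weeks 12 and 28 had 138 decreases in common, against 8.89 for independent lists of these sizes, weeks 5 and 28 had 188 against 36.2, and weeks 5 and 12 had 105 against 6.34. Across 13487 genes, which are not independent replicates, the log2 fold changes of weeks 5 and 12 correlated with Pearson's r of 0.24 and Spearman's rho of 0.23, those of weeks 5 and 28 with 0.36 and 0.22, and those of weeks 12 and 28 with 0.47 and 0.35. The ages share no library, but 1 spread per gene was estimated over all of them. Limma called 1999 genes in the average, 920 higher and 1079 lower, Cck among the higher ones (0.88, adjusted p = 0.000309) with 98.1 ± 15.6 FPKM in the transgenic week 5 libraries. Without the 3 libraries with both Xist and Y-linked genes the count was 1294, and with library weights 4014.

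The interaction of genotype and age asks whether the genotype effect differed between ages. From week 5 to week 12, the effect on 7 of 23 myelin and 4 of 22 cholesterol synthesis genes moved up, away from the lower values at week 5. The list medians of blood and choroid plexus genes had the same sign, at 1.27 and 1.58, camera adjusted p = 0.0837 and 5.07e-07, adjusted p = 0.639 for both with an estimated correlation and fry adjusted p = 0.506 for both (limma). The Cck-/- week 5 libraries, which enter this difference, had the highest mean level of the 6 groups for myelin, cholesterol synthesis and blood genes. Of 23 myelin genes 7 had a higher effect at week 12 (18 higher and 0 lower when adjusted over the list alone), among them Fa2h (0.68 ± 0.10), Ugt8a (0.80 ± 0.13), Cnp (0.60 ± 0.10) and Mog (0.90 ± 0.16; log2 difference ± SE). For the myelin list, camera gave adjusted p = 9.28e-22, adjusted p = 0.215 with an estimated correlation and fry adjusted p = 0.0184 (limma). Of 22 cholesterol synthesis genes 4 did (17 higher and 0 lower when adjusted over the list alone), including Sc5d, Cyp51 and Hmgcs1, by 0.65, 0.70 and 0.79, with camera adjusted p = 8.29e-18, adjusted p = 0.215 with an estimated correlation, fry adjusted p = 0.0184 (limma); Sc5d no longer passed without Cck-/- week 5 replicate 2 (adjusted p = 0.0692), nor Cyp51 and Hmgcs1 without transgenic week 12 replicate 2 (0.113 and 0.132). Of the 12 libraries, leaving out any of 5 ended the call of Sc5d, 11 that of Cyp51 and 10 that of Hmgcs1. Genes with a lower effect at week 12 included Tuba1c (-2.36 ± 0.32), Cck (-2.10 ± 0.32), Pla2g4e (-1.43 ± 0.17) and Scg5 (-1.08 ± 0.11), and genes with a higher effect the elastin gene Eln (1.18 ± 0.19) and Rhbdf2 (0.92 ± 0.11). Limma called 90 genes, 61 with a higher and 29 with a lower effect at week 12. The count was 55, 47 and 43 without Cck-/- week 5 replicate 1, 2 or 3, 56 and 51 without Cck-/- week 12 replicate 1 or 3, 59 without transgenic week 5 replicate 2 and 44 without transgenic week 12 replicate 2. It was 39 with the choroid plexus level as a covariate, 32 without the 3 libraries low in it (1 transgenic week 5 library is then left, and other groups supply the spread), 28 without those with both Xist and Y-linked genes and 367 with library weights. Cck stood at 98.1 ± 15.6 FPKM in the transgenic week 5 libraries used here. A change of the transgene's effect with age thus cannot be told apart from what goes with that level.

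From week 12 to week 28, limma called 0 genes for the interaction, with 1365 of 13487 at an unadjusted p under 0.05. None of the 5 genes named by the rule passed: Sema6d (0.39), Ctxn3 (-1.14), Map4k5 (0.27), Nppb (0.86) and Eps8l2 (-0.54) each had an adjusted p of 0.354 (limma). For Pcp2 the difference was -1.07, SE 0.26, adjusted p = 0.394 (limma). In the Purkinje cell identity list no member passed over all genes, while 19 of 27 had a lower effect at week 28 when adjusted over the list alone. For the Purkinje cell identity list, camera gave adjusted p = 1.57e-15, adjusted p = 0.476 with an estimated correlation and fry adjusted p = 0.152 (limma). The count was 149, of which 131 lower, without transgenic week 28 replicate 3, 1 without Cck-/- week 12 replicate 3, 102 without the 3 libraries low in choroid plexus genes and 2344 with library weights.

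From week 5 to week 28, the effect on 15 of 27 Purkinje cell identity genes moved down, and that on 13 of 23 myelin and 7 of 22 cholesterol synthesis genes moved up. The Cck-/- week 5 libraries, highest of the 6 groups for myelin, cholesterol synthesis and blood genes, enter this difference too. In Cck-/- and transgenic libraries, the mean log2 level of blood genes was 6.64 and 5.16 at week 5 and 5.74 and 4.81 at week 28. For choroid plexus genes it was 3.19 and 1.87, then 3.19 and 2.46. Of 27 Purkinje cell identity genes 15 had a lower effect at week 28 (0 higher and 24 lower when adjusted over the list alone), including Icmt (-1.05 ± 0.18), Itpka (-1.06 ± 0.20), Rgs8 (-1.23 ± 0.24) and Pde5a (-0.69 ± 0.15; log2 difference ± SE). For the Purkinje cell identity list, camera gave adjusted p = 1.84e-18, adjusted p = 0.204 with an estimated correlation and fry adjusted p = 0.00894 (limma). Of 29 calcium and mGluR1 genes 12 did, including the inositol trisphosphate receptor gene Itpr1 (-1.50 ± 0.27) and Cacna1g (-0.96 ± 0.20), with camera adjusted p = 1.34e-11, adjusted p = 0.322 with an estimated correlation, fry adjusted p = 0.0213 (limma), and 5 of the 6 genes first reported lower in SCA1 Purkinje cells. For the SCA1 Purkinje list, camera gave adjusted p = 2.45e-07, adjusted p = 0.204 with an estimated correlation and fry adjusted p = 0.00894 (limma). In the myelin list 13 of 23 had a higher effect at week 28 (21 higher and 0 lower when adjusted over the list alone), among them Fa2h (0.79 ± 0.10), Ugt8a (0.96 ± 0.13), Cnp (0.64 ± 0.10) and Cldn11 (1.14 ± 0.19). For the myelin list, camera gave adjusted p = 5.8e-20, adjusted p = 0.204 with an estimated correlation and fry adjusted p = 0.00894 (limma). In the cholesterol synthesis list 7 of 22 did, including Cyp51 (0.75 ± 0.14) and Sc5d (0.62 ± 0.12). For the cholesterol synthesis list, camera gave adjusted p = 2.85e-12, adjusted p = 0.204 with an estimated correlation and fry adjusted p = 0.00894 (limma). Tuba1c (-2.94 ± 0.32) and Cck (-1.83 ± 0.32) had lower effects at week 28, and stood at 20.9 ± 1.47 and 98.1 ± 15.6 FPKM in the transgenic week 5 libraries. Here too, a change of the transgene's effect with age cannot be told apart from what goes with that level of Cck. Without transgenic week 28 replicate 1, Pde5a, Cacna1g, Sc5d and Pcp2 no longer passed by limma (adjusted p of 0.0679, 0.0679, 0.0504 and 0.119), and Pcp2 (-0.996, adjusted p = 0.0454 with all libraries) did not pass without any of 11 of the 12. Limma called 492 genes, 233 with a higher and 259 with a lower effect at week 28. The count was 189, 192 and 131 without Cck-/- week 5 replicate 1, 2 or 3, 132 and 258 without Cck-/- week 28 replicate 2 or 3, 249, 235 and 272 without transgenic week 5 replicate 1, 2 or 3, 120 and 139 without transgenic week 28 replicate 1 or 2 and 1058 without replicate 3. It was 189 when only these 12 libraries were fitted, 65 without the 3 libraries with both Xist and Y-linked genes and 4325 with library weights.

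Age effects compare libraries of 1 genotype at different ages. In Cck-/- libraries, 20 of 23 myelin genes, 19 of 22 cholesterol synthesis genes and 5 of 12 genes of oligodendrocyte precursors fell between weeks 5 and 12. The levels of markers of other tissue were lower at week 12 too: blood genes went from a mean log2 level of 6.64 ± 0.37 to 5.37 ± 0.77 and choroid plexus genes from 3.19 ± 0.17 to 2.51 ± 0.23 (± SD, n = 3), though neither list passed camera (adjusted p = 0.0828 and 0.0804, 0.873 for both with an estimated correlation) or fry (adjusted p = 0.250 and 0.544; limma). For 79 genes the 3 Cck-/- week 5 libraries lay outside the range of the other 15, with a group mean at least 0.5 (log2) from each of the other groups. Of 23 myelin genes 20 fell and 0 rose, among them Fa2h, Ugt8a, Gsn and Mog by 1.30, 1.58, 1.70 and 1.46 on the log2 scale. For the myelin list, camera gave adjusted p = 2.28e-27, adjusted p = 0.113 with an estimated correlation and fry adjusted p = 2.19e-05 (limma). Of 22 cholesterol synthesis genes 19 fell, including Fdps, Hmgcs1 and Sqle at -0.58, -1.12 and -0.98. For the cholesterol synthesis list, camera gave adjusted p = 4.01e-19, adjusted p = 0.113 with an estimated correlation and fry adjusted p = 8.94e-05 (limma). Of 12 genes of oligodendrocyte precursors 5 fell, including Gpr17 (-1.05), Olig2 (-0.56) and Enpp6 (-0.99). For the precursor list, camera gave adjusted p = 6.54e-06, adjusted p = 0.351 with an estimated correlation and fry adjusted p = 0.00373 (limma). Of 15 circadian clock genes 8 rose, including Hlf (0.58), Bhlhe41 (0.40) and Nr1d2 (0.34), with camera adjusted p = 0.000115, adjusted p = 0.248 with an estimated correlation, fry adjusted p = 0.000731 (limma); the labels give no time of day. Etnppl, an enzyme gene of phospholipid turnover, rose by 1.69, the alarmin gene Il33 by 1.52 and the Polycomb gene Cbx7 by 0.91. Limma called 1595 genes, 714 higher and 881 lower at week 12. The count was 1046, 976 and 986 without week 5 replicate 1, 2 or 3, 955 without week 12 replicate 1, and 3907 with library weights.

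Between weeks 12 and 28 in Cck-/- libraries, 6 of 15 immediate early genes, which neurons switch on with activity, fell and 0 rose, among them Nr4a2, Nr4a3 and Fosl2 at -1.72, -2.08 and -1.03. For the immediate early gene list, camera gave adjusted p = 0.000253, adjusted p = 0.931 with an estimated correlation and fry adjusted p = 0.0117 (limma). Clock genes moved both ways, 4 higher and 4 lower of 15, with Cry1 at -0.67, Per1 at -0.86 and Nr1d1 at 0.42; the list's median of 0.025 and mean of -0.032 differ in sign. For the clock list, camera gave adjusted p = 0.881, adjusted p = 0.931 with an estimated correlation and fry adjusted p = 0.941 (limma). Cx3cr1 and Laptm5 rose by 0.62 and 0.55 among 4 homeostatic microglia genes of 22 that did, with camera adjusted p = 1.78e-06, adjusted p = 0.931 with an estimated correlation, fry adjusted p = 0.173 (limma), but Cx3cr1 did not pass without week 12 replicate 1 (adjusted p = 0.0572, the highest of 3 such libraries) nor Laptm5 without week 28 replicate 1 (0.0642, of 4). Eomes, a transcription factor gene of unipolar brush cells, changed by -1.75, Cpne8 by -1.84, Cck by -1.35 and the nuclear RNA gene Neat1 by 0.96. Eomes, Cpne8, Cck, Nr4a2 and Nr4a3 fell by at least 1 (log2) in transgenic libraries as well. Such a step in both genotypes cannot be told apart from a batch of week 28 libraries, as described further on. Among the changes with small p values were Nox1 (2.12), Srsf4 (-1.74), Dynlt1a (2.29) and the pseudogenes Rpl14-ps1 (2.11) and Rpl31-ps12 (-2.56), whose loci in the file overlap those of other listed genes, so that the assignment of their reads is uncertain. In the same step meninges genes went from a mean log2 level of 3.38 ± 0.17 to 3.79 ± 0.46 and choroid plexus genes from 2.51 ± 0.23 to 3.19 ± 0.45 (± SD, n = 3), with camera adjusted p = 0.00675 and 0.0640, adjusted p = 0.931 and 0.931 with an estimated correlation and fry adjusted p = 0.371 and 0.708 (limma). Limma called 1301 genes, 543 higher and 758 lower at week 28. The count was 713, 691 and 635 without week 12 replicate 1, 2 or 3, 819 and 707 without week 28 replicate 2 or 3, 140 when only these 6 libraries were fitted and 4244 with library weights.

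Between weeks 5 and 12 in the transgenic libraries, Cck went from 98.1 ± 15.6 to 14.8 ± 2.21 FPKM and fell by 2.65 on the log2 scale (SE 0.23, adjusted p = 1.76e-05; limma), together with Tuba1c (-2.83), Pla2g4e (-1.33) and Scg5 (-0.84). Etnppl rose by 2.07, Ctxn3 by 1.43 and Il33 by 1.24. Of 23 myelin genes 8 fell, including Fa2h (-0.61), Ugt8a (-0.78) and Gsn (-0.70), with camera adjusted p = 5.97e-11, adjusted p = 0.538 with an estimated correlation, fry adjusted p = 0.111 (limma), and Gpr17 was the single called precursor gene (-0.83). The antigen presentation genes B2m and H2-K1 rose by 0.73 and 1.00, and the histocompatibility genes H2-T23 and H2-T9 by 0.98 and 0.88. H2-T9 averaged 3.62 FPKM in the transgenic week 5 libraries, which all lay below the other 15 (5.02 to 9.89). Results for H2-T23 and H2-T9 without single libraries are not given here. Without transgenic week 12 replicate 2, B2m and H2-K1 no longer passed (adjusted p of 0.156 and 0.163 by limma), and Gsn did not without week 12 replicate 3 (0.0616). Limma called 161 genes, 80 higher and 81 lower at week 12, and the choroid plexus median changed by 0.96 with the low week 5 replicates 1 and 2. The count was 85 and 102 without week 5 replicate 1 or 3, 68 and 76 without week 12 replicate 2 or 3. It was 28 when only these 6 libraries were fitted, 61 with the choroid plexus level as a covariate, 46 without the 3 libraries low in it (week 5 replicate 3 is then alone, and other groups supply the spread), and 44 without those with both Xist and Y-linked genes.

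Between weeks 12 and 28 in the transgenic libraries, 19 of 27 Purkinje cell identity and 15 of 35 oxidative phosphorylation genes fell, and 19 of 22 homeostatic and 8 of 18 activated microglia genes rose. Markers of other tissue changed level in the same libraries (mean log2 ± SD, n = 3): brainstem and cerebellar nuclei genes from 2.82 ± 0.23 to 3.41 ± 0.39, midbrain and forebrain genes from 1.54 ± 0.24 to 1.99 ± 0.44, meninges genes from 3.68 ± 0.28 to 4.04 ± 0.25, blood genes from 5.45 ± 0.58 to 4.81 ± 0.40 and choroid plexus genes from 3.08 ± 0.61 to 2.46 ± 1.18. Of these lists only that of meninges passed camera (adjusted p = 0.0207, 0.726 with an estimated correlation), and none passed fry (adjusted p of 0.138 to 0.678; limma). Of 27 Purkinje cell identity genes 19 fell, including Itpka, Icmt, Stac and Rgs8 at -1.10, -0.96, -0.81 and -1.09. For the Purkinje cell identity list, camera gave adjusted p = 2.04e-10, adjusted p = 0.611 with an estimated correlation and fry adjusted p = 0.00237 (limma). Pcp2 changed by -1.03 ± 0.18 here and by 0.04 ± 0.18 in Cck-/- libraries, and the difference of these changes did not pass, as given above. Both SEs come from the spread shared by all groups. At week 28 the SD of Pcp2 was 135 FPKM in transgenic and 33.5 in Cck-/- libraries. Of 29 calcium and mGluR1 genes 15 fell and 1 rose, with Atp2a3 and Homer3 at -1.10 and -0.88 and camera adjusted p = 3.01e-06, adjusted p = 0.611 with an estimated correlation, fry adjusted p = 0.00998 (limma). Of 22 homeostatic microglia genes 19 rose, including P2ry13 (0.74), Sall1 (0.57), Cx3cr1 (0.86) and Laptm5 (0.74). For the homeostatic microglia list, camera gave adjusted p = 2.17e-10, adjusted p = 0.611 with an estimated correlation and fry adjusted p = 0.00816 (limma). Of 18 activated microglia genes 8 rose, including Csf1 (0.56) and Clec7a (0.64), with camera adjusted p = 9.02e-05, adjusted p = 0.611 with an estimated correlation, fry adjusted p = 0.0300 (limma), and C4b rose by 1.47. Of 35 oxidative phosphorylation genes 15 fell, including Cox7c, Ndufa1, Atp5o and Cyc1 at -0.58, -0.40, -0.32 and -0.25. For the oxidative phosphorylation list, camera gave adjusted p = 3.78e-07, adjusted p = 0.660 with an estimated correlation and fry adjusted p = 0.0181 (limma). Of 41 mTORC1 pathway genes 5 rose and 11 fell: Sesn1 and Akt1s1, which encode inhibitors of the complex, and Akt2 changed by -0.38, -0.23 and -0.48, and Nprl3, of the inhibitory GATOR1 complex, by 0.30. For the mTORC1 list, camera gave adjusted p = 0.118, adjusted p = 0.611 with an estimated correlation and fry adjusted p = 0.00237 (limma).

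Nr4a2, Nr4a3 and Cpne8 fell in the transgenic libraries too, by 1.21, 1.60 and 2.65 on the log2 scale, and the clock genes Ciart and Bhlhe41 rose by 0.57 and 0.41. Limma called 3216 genes, 1370 higher and 1846 lower at week 28. Of these, 508 decreases and 340 increases were shared with the same age step in Cck-/- libraries, against 104 and 55.2 for independent lists, and the log2 changes correlated across genes with Pearson's r of 0.60 and Spearman's rho of 0.59. The count was 1951 and 1992 without week 12 replicate 2 or 3, 1773 and 1756 without week 28 replicate 1 or 2, 1368 when only these 6 libraries were fitted, 984 without the 3 libraries with both Xist and Y-linked genes and 5128 with library weights. For 20 genes all 6 week 28 libraries lay outside the range of the other 12, with both week 28 group means at least 1 (log2) from each of the other 4, against 1 for week 5 and 0 for week 12, so the step to week 28 cannot be separated here from a batch of week 28 libraries.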

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

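Tests of shared loci, of a week 28 batch and of a lower Purkinje cell share, and the neighbour counts in comparisons other than the genotype effect at week 5, were chosen after the results were seen; the flank, outside-tissue, choroid plexus and week 5 neighbour tests and the splits of the libraries were not. Genotype effects that differed between ages by the interaction test drew attention. From week 5 to 12 there were 90 such genes by limma. The log2 differences were -2.10 for Cck, -2.36 for Tuba1c, -1.08 for Scg5, -1.43 for Pla2g4e, 1.18 for Eln and 0.92 for Rhbdf2. For myelin genes they were 0.68 (Fa2h), 0.80 (Ugt8a), 0.60 (Cnp) and 0.90 (Mog), with a list median of 0.60, and for cholesterol synthesis 0.65 (Sc5d), 0.70 (Cyp51) and 0.79 (Hmgcs1), with a median of 0.40. Leaving out 1 library took the count of 90 to between 43 and 95, with Cck-/- week 5 replicates 1, 2 and 3 (55, 47 and 43), Cck-/- week 12 replicates 1 and 3 (56 and 51), transgenic week 5 replicate 2 (59) and transgenic week 12 replicate 2 (44) each moving it over 1.5 times.

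From week 5 to 28 there were 492 such genes. The log2 differences were -1.83 for Cck, -2.94 for Tuba1c, -0.996 for Pcp2, -1.50 for Itpr1, -1.23 for Rgs8, -1.05 for Icmt, -1.06 for Itpka, -0.69 for Pde5a and -0.96 for Cacna1g. Lists had medians of -0.71 (Purkinje cell identity), -0.47 (calcium and mGluR1 signalling) and -0.86 (first reported lower in SCA1 Purkinje cells). The differences were 0.79 for Fa2h, 0.96 for Ugt8a, 0.64 for Cnp and 1.14 for Cldn11, with a myelin median of 0.69, and 0.75 for Cyp51 and 0.62 for Sc5d, with a cholesterol synthesis median of 0.44. Without transgenic week 28 replicate 1, 2 or 3 the count was 120, 139 or 1058, without transgenic week 5 replicate 1, 2 or 3 it was 249, 235 or 272, without Cck-/- week 5 replicate 1, 2 or 3 it was 189, 192 or 131, and without Cck-/- week 28 replicate 2 or 3 it was 132 or 258.

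Cck was higher in the transgenic than in the Cck-/- libraries at week 5. An allele with a segment of another strain around it predicts more calls near Cck. The odds ratio of a call within 20 Mb was 0.457 (95% interval 0.194 to 0.920, Fisher's exact p = 0.0275, with genes taken as independent). This argues against a segment that changed a large share of the genes within 20 Mb, of which 8 of 217 were called. A short segment, or one that changed few genes, could be missed beside the 1026 calls elsewhere, so it stays open. Tissue from outside the cerebellum predicts higher midbrain or brainstem genes, but the higher of the 2 list medians was -0.11 (log2, 3 and 5 members measured), which argues against such tissue. Chromosome blocks from a mixed background stay open. Genes called at week 5 had a called neighbour 1.05 times as often as in random placements (SD 0.102), against 0.995 for Cck-/- week 12 to 28. The transgenic week 5 to 12 calls gave 5.54 (SD 0.750, reached by none of 1000 placements) and the averaged effect 1.14 (SD 0.048, reached by a share of 0.003). The interaction to week 28 gave 1.62 (SD 0.236, 0.009) and that to week 12, on 4 genes, 3.46 (SD 1.32, 0.111). Comparisons without the transgenic week 5 libraries gave at most 1.35 (SD 0.658, 0.388), on 6 genes at week 12. Among them, the genotype effect at week 28 gave 1.12 (SD 0.075, 0.056), close to the averaged effect. An allele without such a segment, and a difference between the animals in the state of Cck, were not tested and stay open.

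Some genes stepped between weeks 12 and 28 in both genotypes. Reads assigned differently among genes that share a locus is a candidate explanation for a part of them: 13 of 25 step genes (52%) had a locus overlapping that of another listed gene, against 17.5% of other tested genes (odds ratio 5.11, 95% interval 2.15 to 12.3, Fisher's exact p = 9.14e-05). A separate week 28 batch stays open, since batch and age cannot be told apart here: 20 genes had their 6 week 28 libraries apart from the other 12, against 1 for week 5 and 0 for week 12. An earlier form of this test, genes at 0 in the other 12 libraries, gave 2 against 0. An effect of age itself stays open and was not tested against a batch.

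Purkinje cell genes were lower in transgenic libraries at week 28. A difference in choroid plexus or dissection as measured by choroid plexus genes is argued against, since the list median was -1.09 with that level as a covariate and -1.02 without. A lower share of Purkinje cells as the whole cause predicts equal changes in the 7 genes taken as restricted to these cells, which ranged from -1.99 (Car8) to -1.02 (Slc1a6). Cochran's Q over them was 22.0 on 6 degrees of freedom, but Car8 and Pcp2 had been seen before the test was written, and Q did not pass the 0.05 threshold without Car8 (chi-square p = 0.0746) or without both (p = 0.0574). At week 5, Q gave chi-square p = 0.0117 without Car8 and 0.00810 without both, and at week 12 it gave 0.0797 and 0.323. Q takes the genes as independent, but they were measured in the same libraries, so it cannot decide the question. A lower share as the whole or a part of the cause, a difference of the transgene's effect on each gene, and a mixture of these stay open.

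For comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05, and only the real count and the highest of the others are given: 1035 and 0 at week 5, 183 and 0 at week 12, 1439 and 575 at week 28 (575 with transgenic replicates 1 and 2 and Cck-/- replicate 1 on the same side), 1595 and 0 for Cck-/- week 5 to 12, 1301 and 2 for Cck-/- week 12 to 28, 161 and 0 for transgenic week 5 to 12, and 3216 and 179 for transgenic week 12 to 28. Counts of 0 are by limma. For the averaged effect the real grouping was counted among the 100 drawn splits, and it alone gave as many genes (1 of 100, highest other 551). This is the smallest share that 100 splits can give, and it lies under the 0.05 set for it. The same held for the interactions from week 5 to 12 (1 of 100, highest other 6) and from week 5 to 28 (1 of 100, highest other 1). There the reassigned deviations still held any interaction, so the other counts do not show what chance alone would give. For week 12 to 28 the real count was 0 (limma, 1365 at an unadjusted p under 0.05), which every split reaches, so the splits test nothing there (highest other 158, median 0). What lies behind the 158 was not tested. Camera called 9 lists at week 5 and between 5 and 13 in the other splits, 12 at week 28 against 9 to 20, and 6 for Cck-/- week 12 to 28 against 8 to 19, so its counts do not single out the real grouping. Fry called 6 lists at week 5 and 4 at week 12 (0 in every other split of either), 10 at week 28 against at most 8, 4 for Cck-/- week 5 to 12 and 1 for transgenic week 5 to 12 (0 in every other split of either), and 10 for transgenic week 12 to 28 (0). For Cck-/- week 12 to 28 it called 1 list, fewer than the 4 of another split.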

How the results depend on the processing

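The fits without 3 libraries low in choroid plexus genes and without 3 with both Xist and Y-linked genes were chosen after the results were seen. Of 3948 alternative values for 259 named gene results, 3787 kept direction and side of the threshold, 148 no longer passed, 13 newly passed and 0 reversed (limma), and 35 results no longer passed without 1 library. Of 168 counts of calls under other alternatives, 138 lay within 1.5 times. With fits of the compared groups only, fewer libraries estimate the spread. For the rest, the cause was not tested. Counts of calls with library weights were 3112 (week 5), 323 (week 12), 5835 (week 28), 4014 (averaged), 367, 2344 and 4325 (interactions week 5 to 12, 12 to 28 and 5 to 28), 3907 and 4244 (Cck-/- week 5 to 12 and 12 to 28) and 5128 (transgenic week 12 to 28). With only the compared groups they were 63 (week 12), 337 (week 28), 189 (interaction 5 to 28), 140 (Cck-/- 12 to 28), 28 and 1368 (transgenic 5 to 12 and 12 to 28). With the choroid plexus covariate they were 39 (interaction 5 to 12) and 61 (transgenic 5 to 12), and at week 5 695 against 1035. Without the low choroid plexus libraries they were 309 (week 5), 32 and 102 (interactions 5 to 12 and 12 to 28) and 46 (transgenic 5 to 12). The 309, 32 and 46 come from fits with 1 transgenic week 5 library left, assumed to vary like the other libraries, which supply the spread. Without the Xist and Y-linked libraries they were 666, 63 and 668 (weeks 5, 12 and 28), 1294 (averaged), 28 and 65 (interactions 5 to 12 and 5 to 28), 44 and 984 (transgenic 5 to 12 and 12 to 28).

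Leaving out 1 library gave 458 to 802 (week 5), 59 to 210 (week 12), 618 to 1983 (week 28), 1592 to 2550 (averaged), 43 to 95, 0 to 149 and 120 to 1058 (interactions 5 to 12, 12 to 28 and 5 to 28), 955 to 1214 and 635 to 1301 (Cck-/- 5 to 12 and 12 to 28), 68 to 127 and 1756 to 3546 (transgenic 5 to 12 and 12 to 28). Camera with an estimated correlation called 0 of 32 lists in each of the 11 comparisons. Directional fry called 6, 4 and 10 lists (weeks 5, 12 and 28), 15 (averaged) and 3, 0 and 5 (interactions 5 to 12, 12 to 28 and 5 to 28). For age effects it called 4 and 1 (Cck-/- 5 to 12 and 12 to 28) and 1 and 10 (transgenic 5 to 12 and 12 to 28). Mixed fry called 12, 5 and 18, then 18, then 3, 1 and 12, then 12 and 7, and 5 and 17, in the same order. The values give no clear sign that replicate numbers pair the libraries, though 9 pairs cannot rule it out. Deviations of same-number libraries of the 2 genotypes at the same age had a mean correlation of 0.0876 (4 of 9 over 0.1, from -0.160 to 0.435). Those of other numbers had -0.0461 (7 of 18), and 6 of 18 libraries correlated best with their own number. As a block they gave 1007, 192 and 1411 calls at weeks 5, 12 and 28. Depth is unknown, so its limits cannot be given.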

Other observations

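The values here were picked after the results were seen, from lists fixed before. Averaged over ages, the inhibitory interneuron list had 7 of 14 higher and 0 lower, camera adjusted p = 0.00504, adjusted p = 0.466 with an estimated correlation, fry adjusted p = 0.0203 (limma); the average includes the transgenic week 5 libraries, in which Cck stood at 98.1 ± 15.6 FPKM. Between weeks 12 and 28 in transgenic libraries, the reactive astrocyte list had 6 of 18 higher and 0 lower, camera adjusted p = 0.000860, adjusted p = 0.611 with an estimated correlation, fry adjusted p = 0.0332 (limma), and the clock list had 6 of 15 higher and 3 lower, camera adjusted p = 0.0278, adjusted p = 0.611 with an estimated correlation, fry adjusted p = 0.00946 (limma). Between weeks 5 and 12 in Cck-/- libraries, the oxidative phosphorylation list had 1 of 35 higher and 10 lower, camera adjusted p = 7.04e-06, adjusted p = 0.873 with an estimated correlation, fry adjusted p = 0.184 (limma).

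A strain background that differs in the transgenic week 5 animals was looked for in several ways, of which only the neighbour count of the week 5 calls (ratio 1.05, 32.6% of random placements at least as high) was set in advance. Afterwards, 17 genes set apart in these libraries (all 3 outside the range of the other 15, the group mean at least 0.5 on the log2 scale from each of the others) gave a ratio of 71.4, which none of the 1000 random placements reached and which rests on 3 genes of 1 near-identical family. By the same rule 79 genes were set apart in Cck-/- week 5 libraries (ratio 4.94, a share of 0.068 of random placements at least as high) and 122 in transgenic week 28 libraries (2.96, a share of 0.078). The transgenic week 5 group thus did not have the most such genes. Age or genotype effects can set genes apart too, so these counts do not test the background. Outside the family, the 17 included Scg5, Pla2g4e and Fam227b on chromosome 2, between positions 113776313 and 126152004. On chromosome 9 they included Dpy19l1, Clmp and Nxpe4, between 24411779 and 48400025, and Cck. On chromosome 17 they included H2-T9 (from 36038409) and a predicted gene that ends at 35953317. This predicted gene stood at 1.96 ± 0.665 FPKM in the transgenic week 5 libraries and at most 0.0314 in the other 15. The rest lay on chromosomes 3 and 15. The ratio counts only adjacent tested genes, and wider clustering was not tested. Of 161 genes called between weeks 5 and 12 in transgenic libraries, 19 had a called neighbour against 3.43 at random. Of these 19, 5 belong to a family of near-identical genes on chromosome 2, whose reads may be shared. Among chromosomes with a call in this comparison, the share of tested genes called ran from 0.118% on chromosome 5 to 2.51% on chromosome 2. The measures disagree, and the background stays open. The flank test was first worded for any other allele and was narrowed to one with a segment around it after its value was seen. The Purkinje cell share was first looked at in Car8 against Pcp2, before the test over 7 genes.

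Among the 18 libraries, 10 had higher Xist and 8 had higher Y-linked genes, and in 3 (transgenic week 5 replicate 1, week 12 replicate 2 and week 28 replicate 1) both were at 1% or more of their highest library. Sex is not given in the labels. Y-linked genes were the higher in Cck-/- replicates 2 and 3 and transgenic replicate 2 at week 5. At week 12 they were the higher in Cck-/- replicates 2 and 3 and transgenic replicate 3, and at week 28 in replicate 1 of each genotype. By these genes, sex was not balanced in the genotype effects at weeks 5 and 12 or in the Cck-/- step from week 12 to 28. With Xist as a covariate, 253 of 259 named gene results kept direction and side of the threshold. The 10 most abundant genes held 14.5% of the FPKM sum in transgenic week 28 replicate 2 and 3.41% to 4.20% in the others. The first 2 principal components held 34.1% and 12.2% of the variance.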
